A study of Oryza sativa Japonica Group with 20 samples.

How the data were processed

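Poly(A) RNA and small RNA were profiled in roots and shoots of 14-day-old Nipponbare rice seedlings grown hydroponically, untreated (0 h) or after 6 h or 24 h in 20 or 80 µM sodium arsenite. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was selected with oligo(dT) and primed with random hexamers, and libraries were sequenced as paired-end 75-nt reads on an Illumina Genome Analyzer. The small-RNA library protocol is not given in the sources used here. Each tissue, dose and time had 1 mRNA and 1 miRNA library, so no group has a replicate. Untreated plants were sampled at 0 h only, at the same hour of day as the 24 h plants, which leaves no untreated sample for the 6 h harvest.

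The authors deposited 1 table of RPKM values per mRNA library, with 57624 loci under MSU locus identifiers and values rounded to 1 decimal. Per the submitters' processing notes BWA was among the tools; its version, the genome build, the annotation release and the counting tool are not given in the sources used here. The deposited miRNA tables hold 185 miRNAs, and their names call them RPKM, but the low values of each library are multiples of 1 common step whatever the miRNA, so they are treated as RPM, scaled to library size and not to length, and called values in the text. The miRBase release is not given in the sources used here. Reads could not be recovered as whole numbers for nearly all miRNAs at 1 decimal, and no count model was fitted. For mRNA, comparing low values of the same genes between libraries put the value of 1 read at 0.78 to 1.38 times that of the untreated root library, so relative depth is known and absolute depth is not. An exact 0 is reported as listed at 0, and no fold of a single gene is given against it. Such genes do enter counts, list medians and limma on the log2(RPKM + 1) scale, where the size of their change depends on the pseudocount.

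Values were taken as log2(RPKM + 1), and a gene was considered in a comparison where it reached 5 RPKM in at least 1 of the libraries compared. For miRNAs log2(value + 10) was used with a minimum of 100 in at least 1 library. A log2 change on this scale understates the change of low genes. With 1 library per group, treated and untreated libraries, and the doses, were compared by counting genes at least 2-fold higher or lower on that scale in all 4 treated libraries or at both times, with no test. Because the 4 differences share 1 untreated library, unchanged groups were simulated against it 100 times. Their spread per gene was the residual SD of the within-tissue limma model below, with a median of 0.59 in roots and 0.61 in shoots (log2). That residual measures how dose effects differ between the times, so it is not a spread between replicates. The same rule was run with each of the 5 libraries of a tissue as the reference; since there are 5 choices, the untreated library can rank no better than a share of 0.2. The median change of a gene list with at least 3 measured members was set beside 10000 random lists of equal size matched by decile of mean expression, as a description of these libraries.

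Models of 3 kinds were fitted with limma 3.58.1 (R 4.3.3), with an intensity trend and Benjamini-Hochberg adjustment at 0.05: shoots against roots with the 5 conditions as blocks (4 residual degrees of freedom), dose or time over both tissues with the other 2 factors as blocks (3), and treatment, dose and time within each tissue with their differences between tissues (2). Their residuals measure how an effect varies over conditions, and each lone untreated library is assumed to vary like the others. Adjustment over a list alone took in only that list's members, with no adjustment across the lists or comparisons. Such calls are therefore weaker than calls over all genes. Each model was tested on simulated data with 200 changed genes. The noise in every simulation was the residual SD of the within-tissue model. It leaves out how effects differ between tissues, which is part of the other models' residuals. Of simulated log2 changes of 2 among 18667 genes, the share recovered was 80% for tissue, 64% for dose, 52% for time, 2% for treatment in roots and 12% for dose in roots. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

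The tables give no gene names. The reference table given (RefSeq ASM3414082v1) lists 0 of the MSU identifiers, so names for 183 identifiers were written down from general knowledge of published rice loci and then checked: for 119 the reference lists the symbol on the same chromosome, for 9 more an alias looked up later is listed there, 52 are not listed and are not printed by name, and 3 were dropped because the symbol lies on another chromosome, which leaves 180 identifiers. Of the 128 printable names, 121 have a single place in the reference, and 120 of these run in the same order along their chromosomes as the MSU numbers; OPR1 and AMT1;3 are among those with several places. A name is therefore a published assignment checked by position, not an annotation of these tables. Identifiers of the glutathione S-transferases and the measured SPL genes were not among the 183, so they rest on general knowledge alone. The targets set beside other miRNA families also rest on general knowledge and carry no position check. The 52 identifiers that are not listed still count in their lists. They make up most of the further heat shock, lipid and ethylene lists. What each gene is known to do is background.

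The comparisons, settings, alternatives, 17 gene lists with identifiers and the rule for naming genes were fixed before the data were examined. Another 22 lists rested on gene descriptions, which the sources used here do not give for these identifiers, and are not analysed here; for the same reason the rule's demand for an informative description could not be applied. The 13 lists added later, before the values of their members were read, are the glutathione S-transferases, antioxidant enzymes, zinc, copper and cadmium transport, nitrate and ammonium transport, aquaporins, auxin, gibberellin, lipid genes, WRKY factors, further heat shock genes, phenylalanine ammonia-lyases, cellulose synthases and cell division. The rule named genes with at least 10 RPKM in 1 library of the tissue: the 8 largest increases and decreases over the 4 treated libraries and the 5 largest dose differences each way, per list up to 4 members with the largest change and those listed by name, the 4 largest tissue differences each way, and the 5 largest miRNA changes each way. Genes without a name were limited to 2 higher and 2 lower.

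Alternatives were pseudocounts of 0.1 and 5 (1 and 100 for miRNA), no filter on low values, RPKM rescaled to a common sum, median ratio scaling, no intensity trend, no condition block, leaving out each library, condition or pair in turn, exchanging the 2 shoot mRNA libraries at 20 µM and reassigning 3 shoot miRNA libraries by their header codes. Median ratio scaling takes its factors from the libraries compared. Over the 5 libraries of a tissue it shifted the median of all genes against the untreated library by −0.12 in both root libraries at 20 µM and by 0.25 in the shoot library at 80 µM and 24 h (log2). In single comparisons, scaled over 2 libraries, it shifted them the other way in roots, by 0.13 and 0.12 at 20 µM after 6 h and 24 h and by 0.13 at 80 µM after 24 h, and by 0.18 in shoots at 80 µM and 24 h. Between doses the shift was 0.11 and 0.15 in roots at 6 h and 24 h and 0.17 in shoots at 24 h. Rescaling shifted the root libraries at 6 h by −0.13 and −0.23 in 20 and 80 µM. Taken over all libraries for limma, median ratio scaling shifted values by 0.364 in shoots at 80 µM and 24 h. It shifted roots at 20 µM by −0.151 after 6 h and −0.175 after 24 h. Factors over the treated libraries alone gave 0.367, −0.162 and −0.175 for these libraries in that order. Other shifts were about 0.1 or less in size.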

Results

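The series profiled roots and shoots of 14-day-old seedlings of the japonica rice cultivar Nipponbare after exposure to sodium arsenite, a trivalent form of arsenic, and its title names transporters, plant hormones and lipid metabolism as the pathways of interest. Seedlings were harvested untreated at 0 h and after 6 h or 24 h in 20 or 80 µM arsenite, which gives 5 groups per tissue. Messenger RNA and microRNA (miRNA) were sequenced from each of the 10 groups, so there are 20 libraries with 1 library per group and no replicates. The mRNA tables hold RPKM values, reads scaled to gene length and library size, for 57624 loci. They sum to between 313836 and 369084 per library. Genes at 5 RPKM or more numbered 12515 in the untreated root library, 8016 in the root library at 80 µM and 6 h, and 9129 in the shoot library at 80 µM and 24 h. The miRNA tables hold 185 miRNAs, and their summed values, a part of each library, ranged from 2921.0 to 9093.6. Correlations of log2(RPKM + 1) across genes, which are not independent replicates, were 0.772 to 0.946 between root libraries, 0.841 to 0.950 between shoot libraries and 0.646 to 0.839 between the tissues.

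The clock genes of the shoot libraries labelled 20 µM ran against their time labels. The 0 h and 24 h harvests fell at lights-on and the 6 h harvest 6 h into the light period, so the dawn gene LHY (LOC_Os08g06110) can be set against the day-phase genes GI, PRR1, PRR95 and a further PRR gene as a readout of harvest hour. In roots the log2 difference, LHY minus the mean of the 4 day genes, was 1.91 untreated, −1.15 and −1.97 at 6 h in 20 and 80 µM, 1.45 at 24 h in 20 µM and −1.69 at 24 h in 80 µM, the last nearer to the 6 h roots than to the untreated ones. In shoots it was 3.28 untreated, 0.37 at 80 µM and 6 h, and 6.16 at 80 µM and 24 h. It was 3.09 in the library labelled 20 µM 6 h and 0.27 in the library labelled 20 µM 24 h. The codes written in the headers of these 2 shoot mRNA files are each other's as well. The labels were kept, each of the 2 is called by its label throughout, and every shoot difference that separates 6 h from 24 h at 20 µM carries this doubt.

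**Figure D1:**
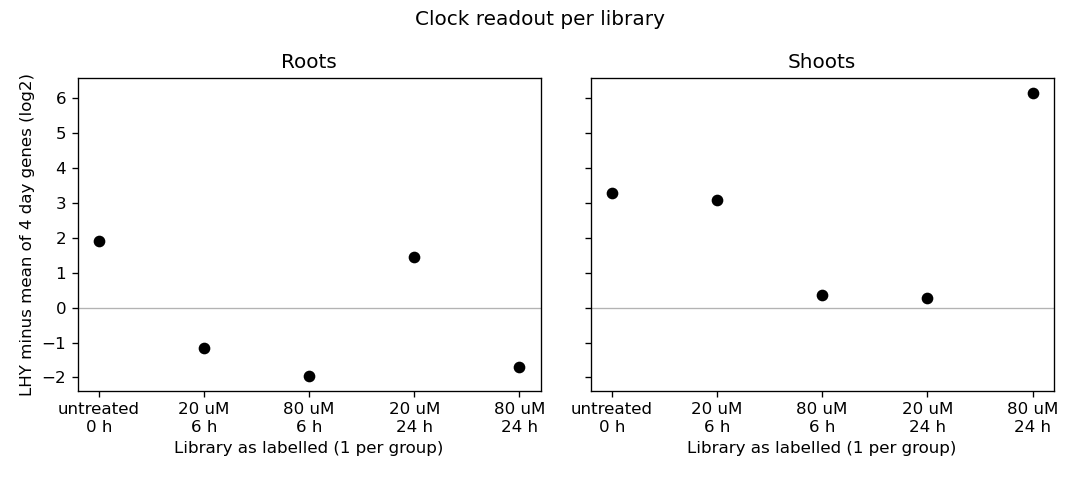
Clock readout of each mRNA library (y axis, LHY minus the mean of 4 day-phase genes, log2 RPKM + 1; x axis, libraries as labelled, 1 point per library, roots left and shoots right). The shoot library labelled 20 µM 6 h, at 3.09, lies near the untreated one at 3.28, and that labelled 20 µM 24 h, at 0.27, near the 80 µM 6 h library at 0.37.

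In roots, the silicon and arsenite transporter genes Lsi1, Lsi2 and Lsi6 stood lower in the treated libraries than in the untreated one. Lsi1 (LOC_Os02g51110), the channel by which rice roots take up silicic acid and arsenite, stood at 59.7 RPKM in the untreated library, at 18.7 and 0.4 RPKM after 6 h in 20 and 80 µM, and at 11.8 and 1.7 RPKM after 24 h. It was at least 3.08-fold lower in all 4 treated libraries. Lsi2 (LOC_Os03g01700), the exporter that works with Lsi1, stood at 103.9 RPKM untreated, at 53.9 and 1.3 RPKM after 6 h and at 13.4 and 5.9 RPKM after 24 h. Lsi6, a related channel, was at 29.4 RPKM untreated and listed at 0 in the 80 µM 6 h library, whereas NIP1;1 went from 0.2 RPKM to 9.6, 3.9, 0.9 and 19.7 RPKM in the same order. Over the 5 measured members of this list the median of the mean log2 changes was −3.03, at percentile 0.0 of 10000 random lists matched on expression. By the 2-fold rule 1 member was lower and 1 higher in all 4 treated libraries, and 2 of the 5 had a positive mean change. The median was −1.91 with a pseudocount of 5, and 1 member is listed at 0 in a library. Limma called 1 member higher and 3 lower when adjusted over the list alone and 0 when adjusted over all genes.

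Several iron acquisition genes were lower in treated roots. YSL15 (LOC_Os02g43410), which imports iron bound to phytosiderophores, went from 78.3 RPKM to 0.7, 0.3, 13.7 and 0.8 RPKM at 20 and 80 µM for 6 h and 20 and 80 µM for 24 h, a mean log2 change of −4.84 ± 1.62 (SD over the 4 treated libraries). The iron importer IRT1 (LOC_Os03g46470) was at least 5.17-fold lower and the manganese and iron importer Nramp5 at least 3.27-fold lower in all 4. Nicotianamine synthases NAS1 and NAS2, which make the phytosiderophore precursor, stood at 297.0 and 344.0 RPKM untreated, at 155.8 and 242.6 RPKM at 20 µM and 24 h, and at 0.9 and 2.6 RPKM at 80 µM and 24 h. The list median over 10 measured iron genes was −2.85 (percentile 0.0), and −0.84 at 20 µM and 24 h, and 2 members had a positive mean change. By the 2-fold rule 3 members were lower and 0 higher in all 4 treated libraries. Of 12 members tested, 2 were called lower by limma adjusted over the list alone. The root uptake markers, which share Lsi1, Lsi2, YSL15, IRT1 and others with these lists, had a median of −3.29 (percentile 0.0). Of these 4 of 6 were lower in all 4, and all 6 were lower by limma adjusted over the list alone.

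Some nitrogen transporters and water channels of roots were also lower. NAR2.1, the partner protein of the nitrate transporters, went from 39.7 RPKM to 9.5, 1.6, 8.0 and 1.9 RPKM and the ammonium transporter AMT1;3 from 20.0 RPKM to 4.3, 4.0, 0.7 and 1.9 RPKM, in the same library order. The nitrogen list had a median of −2.68 over 4 members (percentile 0.0), with 3 lower in all 4. It was −1.73 with a pseudocount of 5 and −0.93 without a filter on low values. The aquaporins PIP2;4 (61.9 RPKM untreated; 7.4 RPKM, a listed 0, 11.5 and 10.1 RPKM treated) and PIP2;3 (57.5 RPKM; 8.0 RPKM, a listed 0, 23.4 and 0.5 RPKM) were lower in all 4 treated libraries. Their list had a median of −2.60 over 11 members (percentile 0.0), with −0.48 at 20 µM and 24 h (percentile 1.57). With a pseudocount of 5 the median over the 4 treated libraries was −1.67, and 3 members are listed at 0 in a library. Of the 11, 3 were lower in all 4, and limma adjusted over the list alone called 7 lower. Phosphate transporters had a median of 0.01 over 7 members (percentile 66.4), which became −0.13 and −0.03 under the alternative scalings. PT8 stood at 85.2 RPKM untreated and 131.5, 168.8, 137.9 and 61.4 RPKM treated. Zinc, copper and cadmium transporters had a median of −0.39 over 5 members (percentile 32.12), and limma called none of either list for the treatment.

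Some jasmonate and abscisic acid genes were higher in treated roots. OPR1 (LOC_Os06g11290), an oxophytodienoate reductase family member, went from 1.6 RPKM to 153.6, 397.5, 96.3 and 260.9 RPKM, a mean log2 change of 6.26 ± 0.89 (SD), and was the only one with a name among the 8 genes with the largest mean increase in roots. The jasmonate synthesis gene AOS2 (38.4 RPKM untreated; 180.5, 221.8, 100.1 and 87.8 RPKM treated) and the repressors JAZ11 and JAZ12 were each at least 2.15-fold higher in all 4. The jasmonate list had 4 of 11 measured members higher in all 4 and 0 lower, a median of 1.13 (percentile 97.84), and 1 of 12 higher by limma adjusted over the list alone. Its median was 1.36 to 1.61 in the other 3 treated libraries and −0.12 (percentile 22.52) at 80 µM and 24 h. Among abscisic acid genes, LEA3 (LOC_Os05g46480), a late embryogenesis abundant protein gene, went from 4.5 RPKM to 38.9, 340.0, 15.9 and 168.0 RPKM and ABA8ox2, an abscisic acid 8'-hydroxylase, from 0.5 RPKM to 10.2, 6.1, 2.9 and 10.5 RPKM. This list had 3 of 6 members higher in all 4, a median of 2.29 (percentile 99.99; 1.07 with a pseudocount of 5) and 1 of 8 higher by limma adjusted over the list alone.

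Genes of the other hormones did not go in 1 direction. In the cytokinin list, RR6, a response regulator, went from 7.9 RPKM to 21.4, 71.6, 36.2 and 55.4 RPKM, with a list median of 0.20 over 3 members (percentile 75.62) that became −0.47 without a filter on low values. Limma tested 4 cytokinin genes, with a median of −0.19, and called 1 higher when adjusted over the list alone. Auxin genes had a median of −0.04 over 4 members (percentile 65.72), with no member past 2-fold in all 4. Of 2 measured gibberellin genes 1 was higher and 1 lower in all 4, limma called 2 of 4 lower when adjusted over the list alone, and the 1 measured ethylene gene was lower in all 4. The lipid genes, a pathway of the series title, had a median of −0.52 over 6 members (percentile 12.12) with 1 higher in all 4. It was −0.29 with a pseudocount of 5 and −0.07 without a filter on low values. The phospholipase D gene PLDa1 stood at 96.5 RPKM untreated and at 60.3, 14.0, 74.4 and 52.4 RPKM treated.

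A sulfate assimilation gene, part of a glutathione S-transferase cluster and a few stress factor genes were higher in treated roots. APR1 (LOC_Os07g32570), which reduces activated sulfate, went from 30.7 RPKM to 219.6, 485.2, 75.8 and 359.3 RPKM, and 1 of the 2 sulfate genes was called higher by limma adjusted over the list alone. Of 9 measured glutathione S-transferase genes clustered on chromosome 10, 5 were higher and 1 lower in all 4, with a median of 2.31 (percentile 99.99; 0.88 with a pseudocount of 5) and 1 of 10 higher by limma adjusted over the list alone. The identifiers of these transferases were not checked against the reference. NAC6, a stress transcription factor, was at least 3.21-fold higher in all 4 treated libraries and WRKY62 at least 4.26-fold, at 68.6 and 26.4 RPKM untreated. The DREB, NAC and MYB list had a median of 0.95 over 6 members (percentile 97.29), with 1 higher in all 4 and 2 higher by limma adjusted over the list alone. The WRKY list had a median of 1.1 over 8 members (percentile 91.95), with 2 higher in all 4 and 1 of 9 higher by limma adjusted over the list alone. Glutathione and phytochelatin synthesis genes had a median of 0.25 over 3 members (percentile 83.46), antioxidant enzymes −0.29 over 8 (percentile 14.93), fermentation −0.37 over 3 (percentile 31.35) and phenylalanine ammonia-lyases 0.15 over 3 (percentile 31.85), with no member of these 4 lists past 2-fold in all 4.

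Leaf photosynthesis genes were highest in the untreated root library. The chlorophyll-binding protein gene CAB2R (LOC_Os01g41710) stood at 56.7 RPKM there and at 6.3, 1.3, 11.9 and 2.1 RPKM in the treated root libraries, and CAB1R at 33.9 RPKM and at 10.0, 2.2, 6.9 and 1.8 RPKM. The 5 photosynthesis genes had a median of −2.72 (percentile 0.0), 4 were lower in all 4, and all 5 were lower by limma adjusted over the list alone. The reference genes ACT1 (185.0 RPKM untreated; 121.4, 31.1, 171.3 and 76.0 RPKM treated) and EF1A (15.9 RPKM; 8.5, 1.6, 16.5 and 5.1 RPKM) were not level across the root libraries. The day-phase clock genes had a median of 0.39 over 6 members (percentile 88.1), and the dawn gene LHY stood at 54.4 RPKM untreated and 11.7, 6.5, 44.7 and 10.1 RPKM treated.

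Of 15414 root genes, 718 were at least 2-fold higher and 1075 at least 2-fold lower in all 4 treated libraries, against 255.7 and 274.1 on average in 100 simulations of unchanged groups sharing 1 control. The spread given to those groups was a model residual and not one between replicates. Among genes without a name in the sources used here, LOC_Os09g20220 went from 4.8 RPKM to 433.9, 945.8, 415.2 and 903.9 RPKM, and LOC_Os06g39240 from 1.0 RPKM to 60.7, 987.6, 24.3 and 983.8 RPKM. LOC_Os09g24370 went from 683.5 RPKM to 70.9 and 7.9 RPKM at 6 h and a listed 0 at 24 h, and LOC_Os02g37190 from 179.8 RPKM to 11.9, 1.4 and 3.8 RPKM and a listed 0. Limma called 0 of 18667 genes for the treatment in roots after Benjamini-Hochberg adjustment (2196 at an unadjusted p under 0.05, smallest adjusted p 0.256). This model has 2 residual degrees of freedom and recovered 34% of simulated log2 changes of 3 and 98% of those of 5; without a filter on low values it called 4 genes higher and 355 lower of 31441. A gene listed at 0 in all treated libraries leaves no residual in its tissue. Calls made without the filter can thus rest on the untreated library alone. With a pseudocount of 5 the counts of the 2-fold rule over all 4 libraries were 417 and 439. The same rule with the 80 µM 6 h library as the reference gave 2702 genes against 1793 for the untreated one, and leaving out the 20 µM 24 h or the 20 µM 6 h library raised the lower count to 1801 or 1636. Because the untreated roots were harvested at lights-on, treatment and time of day cannot be told apart at 6 h.

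**Figure D2:**
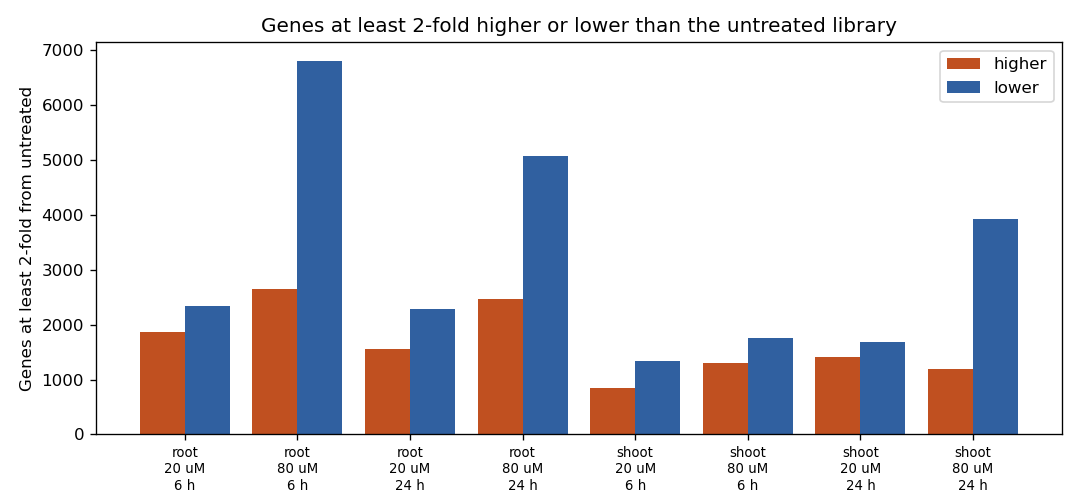
Genes at least 2-fold higher (orange) or lower (blue) than the untreated library of the same tissue (y axis, number of genes; x axis, treated libraries as labelled, 1 library per bar pair). The root library at 80 µM and 6 h had 6794 lower genes, against 2338 at 20 µM and 6 h.

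Each treated root library was also set against the untreated one by itself. At 20 µM, 1871 genes were higher and 2338 lower after 6 h, and 1559 higher and 2279 lower after 24 h. At 80 µM, 2648 genes were higher and 6794 lower after 6 h, and 2467 higher and 5071 lower after 24 h. The median log2 change over genes was −0.224 and −0.205 at 20 µM and −0.928 and −0.473 at 80 µM, after 6 h and 24 h. Under median ratio scaling the balance at 20 µM and 6 h turned, with 2079 higher and 1940 lower. These differences have no replicate check.

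The dose comparison in roots sets libraries labelled with the same harvest hour against each other. Their clock readouts were −1.15 and −1.97 at 6 h in 20 and 80 µM, but 1.45 and −1.69 at 24 h. The 24 h pair thus differed in this readout as well as in dose. Heat shock genes stood out: HSP101 (LOC_Os05g44340), a disaggregase, was at 1.4 RPKM at 20 µM and 141.8 RPKM at 80 µM after 6 h, and was listed at 0 at 20 µM and at 109.2 RPKM at 80 µM after 24 h. The small heat shock protein gene HSP16.9A (LOC_Os01g04370) was at 1.0 and 276.1 RPKM after 6 h and at a listed 0 and 222.5 RPKM after 24 h. The heat stress factor gene HSFA2a was at 0.5 and 44.5 RPKM after 6 h and at a listed 0 and 35.6 RPKM after 24 h. The copper transporter gene HMA5 was at 15.8 and 282.6 RPKM after 6 h and at 34.9 and 240.8 RPKM after 24 h. The 7 heat shock genes had a median dose difference of 6.34 (percentile 100), a size set in part by the pseudocount since 4 of them are listed at 0 in a treated library. It was 4.52 with a pseudocount of 5 and 8.33 with 0.1. The 10 further heat shock genes had a median of 4.41 (percentile 100; 3.75 with a pseudocount of 5). Limma adjusted over each list alone called 4 and 9 of them higher for dose in roots. Over the mean of all 4 treated libraries these 2 lists had medians of 4.02 and 2.58 (both percentile 100), with 1 and 2 members higher in all 4. These come mostly from 80 µM, since at 20 µM the medians were 1.0 and 0.81 after 6 h and 0.0 and 0.04 after 24 h (percentiles 62.38 and 42.44).

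Cellulose synthases, several channels and some iron genes were lower at the higher dose. NAS1 was at 29.5 RPKM at 20 µM and listed at 0 at 80 µM after 6 h, and NAAT1, the next enzyme of phytosiderophore synthesis, was at 14.0 and 2.0 RPKM after 6 h and at 42.6 and 4.7 RPKM after 24 h. The cellulose synthase gene CESA3 was at 39.3 and 4.6 RPKM after 6 h and at 50.3 and 8.7 RPKM after 24 h. The 6 cellulose synthases had a median dose difference of −2.84 (percentile 0.0) and all 6 were lower for dose in roots by limma adjusted over the list alone. Over all 4 treated libraries their median was −2.52 (percentile 0.0), with 2 lower in all 4. The median dose difference was −2.19 for iron genes (percentile 0.01), −2.82 for the silicon and arsenite channels (percentile 0.01) and −1.63 for aquaporins (percentile 0.01), and −0.50 for jasmonate genes (percentile 9.6). With a pseudocount of 5 these medians were −1.32, −1.66, −1.53 and −0.44 in that order. Limma adjusted over each list alone called 3 of 5 channels and 5 of 11 aquaporins lower for dose, and 0 of 12 iron genes. It called both reference genes lower as well, with a median of −1.62.

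**Figure D3:**
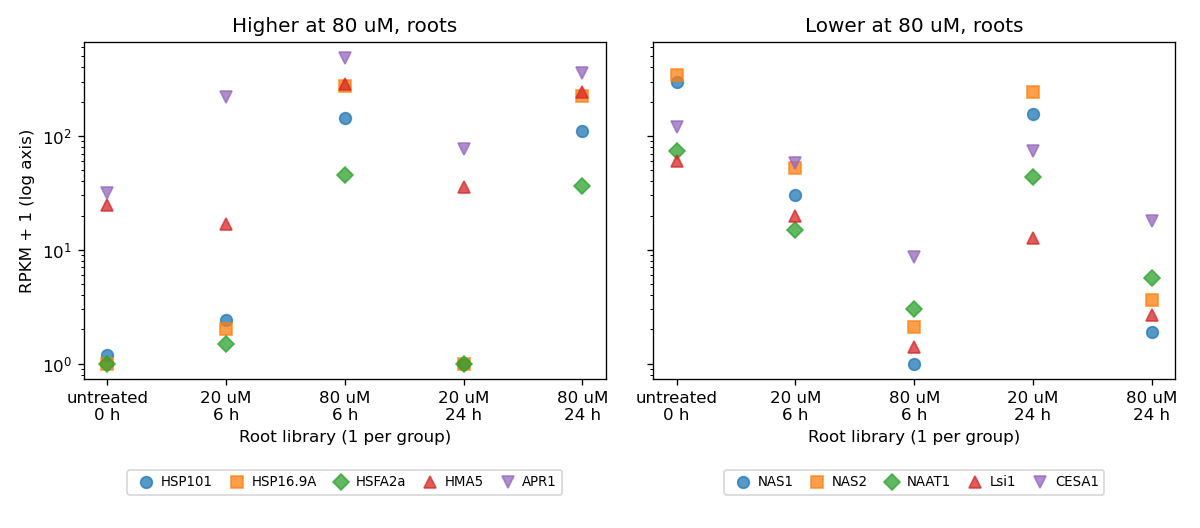
RPKM + 1 on a log axis (y) of 10 genes in the 5 root libraries (x, 1 point per library and gene), with genes higher at 80 µM on the left and lower on the right. HSP101 lies at 141.8 and 109.2 RPKM at 80 µM and at 1.4 RPKM or a listed 0 at 20 µM, and NAS1 at 0 and 0.9 RPKM at 80 µM against 29.5 and 155.8 RPKM at 20 µM.

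Of 13863 root genes, 1062 were at least 2-fold higher and 2324 at least 2-fold lower at 80 than at 20 µM at both times, and 665 and 957 with a pseudocount of 5. The differences at 6 h and at 24 h, which share no library, correlated across genes with Pearson's r of 0.60 and Spearman's rho of 0.56. At single times the counts were 1822 higher and 4599 lower after 6 h and 1983 higher and 3203 lower after 24 h. Limma called 0 of 18667 genes for dose in roots (2892 at an unadjusted p under 0.05, smallest adjusted p 0.160), recovering 52% of simulated log2 changes of 3, and with a pseudocount of 5 it called 5 higher.

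In shoots, LEA3 and the nicotianamine synthase gene NAS3 were lower in all 4 treated libraries. LEA3 stood at 245.1 RPKM in the untreated library, at 1.3 RPKM in the library labelled 20 µM 6 h, 32.9 RPKM at 80 µM 6 h, 1.8 RPKM in the library labelled 20 µM 24 h and 1.5 RPKM at 80 µM 24 h, at least 7.26-fold lower in each. NAS3 stood at 16.7 RPKM and at 5.3, 2.2 and 2.1 RPKM and a listed 0 in that order. NAS1 and NAS2 were at 189.9 and 158.7 RPKM in the library labelled 20 µM 6 h, against 20.0 and 15.2 RPKM untreated, and at 8.8 and 7.2 RPKM at 80 µM 6 h. The 9 measured iron genes had 3 lower and 0 higher in all 4 and a median of 0.25 (percentile 95.72).

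Abscisic acid genes had a median of −0.97 over 8 members in shoots (percentile 0.11), with 2 lower in all 4 and 1 lower by limma adjusted over the list alone. Photosynthesis genes had a median of 0.60 over 5 members (percentile 99.66), with CAB1R at 191.3 RPKM untreated and 243.9, 345.5, 300.7 and 281.5 RPKM treated. Heat shock genes had a median of −0.34 over 7 members (percentile 32.7), and −1.68 with a pseudocount of 0.1. Jasmonate genes had a median of −0.14 over 12 (percentile 36.69), glutathione S-transferases −0.67 over 8 (percentile 3.02), antioxidant enzymes −0.38 over 9 (percentile 3.93) and the silicon and arsenite channels −0.41 over 4 (percentile 14.35). With a pseudocount of 5 the medians were −0.26 for the glutathione S-transferases, of which 3 are listed at 0 in a library, and −0.2 for the channels. Phosphate genes had a median of −0.46 over 5 members (percentile 15.52), cellulose synthases 0.32 over 6 (percentile 96.57) and lipid genes −0.01 over 8 (percentile 67.17), the last turning to 0.09 under median ratio scaling, as the DREB, NAC and MYB list turned from −0.06 to 0.03.

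Of 15408 shoot genes, 77 were at least 2-fold higher and 226 lower in all 4 treated libraries, fewer than the 288.2 and 306 that simulated unchanged groups sharing 1 control gave on average. The simulated spread was a model residual pooled over roots and shoots, not one between replicates, so these averages are no measured background. With the other shoot libraries as the reference the rule gave 317, 360, 563 and 3334 genes, against 303 for the untreated one. With a pseudocount of 5 they were 16 and 120. Limma called 0 of 18667 genes for the treatment in shoots (332 at an unadjusted p under 0.05), and 382 lower without a filter on low values. In single comparisons 842 genes were higher and 1346 lower in the library labelled 20 µM 6 h, 1307 and 1752 at 80 µM 6 h, 1417 and 1691 in the library labelled 20 µM 24 h, and 1192 and 3920 at 80 µM 24 h. The counts over all 4 do not depend on which of the 2 doubted labels is which. Without both libraries labelled 20 µM, an alternative chosen after seeing the data, they were 191 and 554. Without the 80 µM 24 h library 244 were higher, without the library labelled 20 µM 6 h 133 were higher, and without the 80 µM 6 h library 408 were lower.

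Dose differences of shoots did not run in 1 direction at the 2 times. PIP2;6, a water channel, was at 257.2 RPKM in the library labelled 20 µM 6 h and 338.8 RPKM at 80 µM 6 h, and at 402.0 RPKM in the library labelled 20 µM 24 h and 25.0 RPKM at 80 µM 24 h. CESA8 was at 95.1 and 69.4 RPKM and at 93.8 and 13.0 RPKM in the same order, and the 6 cellulose synthases had a median dose difference of −1.28 (percentile 0.04). Abscisic acid genes had a median dose difference of 1.36 (percentile 100) and the 7 heat shock genes one of 1.04 (percentile 99.6), with HSP101 at 1.0 and 8.8 RPKM at 6 h and at 1.6 RPKM and a listed 0 at 24 h. With a pseudocount of 5 these medians were 1.04 and 0.51, and 5 of the 7 heat shock genes are listed at 0 in a treated library. Against untreated shoots the median of the 7 was −1.35 in the library labelled 20 µM 6 h, 1.0 at 80 µM 6 h, −0.84 in the library labelled 20 µM 24 h and −1.68 at 80 µM 24 h, so the dose difference turned between the times. Limma called 0 genes of the abscisic acid (median 0.82 over 8 tested), heat shock, further heat shock and cellulose synthase lists for dose in shoots, adjusted over each list alone or over all genes. At both times 116 of 14950 genes were higher and 320 lower at 80 than at 20 µM; at single times 1788 were higher and 1656 lower at 6 h (1694 and 1724 under median ratio scaling) and 1856 higher and 4094 lower at 24 h. The differences at 6 h and at 24 h correlated across genes with r of −0.314 and rho of −0.311 as labelled. Limma called 0 of 18667 genes for dose in shoots (485 at an unadjusted p under 0.05), and with the libraries labelled 20 µM exchanged the counts at 6 h became 1100 and 951.

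Few genes passed the 2-fold rule in both roots and shoots. Among 12155 genes considered in both tissues, 4 were higher in all 4 treated libraries of both (2.2 for independent lists), 13 were lower in both (9.4) and 24 were higher in roots and lower in shoots (6.2), LEA3 among them. In turn 7 were lower in roots and higher in shoots (3.3). For dose, 60 genes were lower at 80 µM at both times in both tissues (28.6 for independent lists) and 9 were higher (4.1), while 7 and 12 went in opposite directions (10.8 and 10.9). The tissues share no library.

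Heat shock genes and cellulose synthases were called for dose over both tissues only by adjustment over each list alone. In shoots alone 0 of them were called. Limma with tissue and time as blocks called 5 of 7 heat shock genes, 8 of 10 further heat shock genes and 2 of 8 abscisic acid genes higher at 80 µM when adjusted over each list alone, and 6 of 6 cellulose synthases and both reference genes lower. Over all 17905 genes tested it called 0 for dose (1846 at an unadjusted p under 0.05, smallest adjusted p 0.437) and 0 for 24 h against 6 h (350 at an unadjusted p under 0.05). In simulations of these models on 18667 genes, 98% and 96% of log2 changes of 3 were recovered. The simulated noise left out differences between tissues, which these models' residuals hold, so the shares may be too high for these data. Left without the pair of shoot libraries at 24 h, limma called 15 genes higher and 4 lower for dose. The differences in effect between tissues gave 0 calls by limma over all 18667 genes for treatment, dose and time (1251, 1267 and 556 at an unadjusted p under 0.05), and 14% of simulated log2 changes of 5 in the treatment difference were recovered on these genes. Adjusted over each list alone, limma called a larger dose effect in roots for 4 of 7 heat shock and 3 of 10 further heat shock genes, and a lower treatment effect in roots for 4 of 5 photosynthesis genes. Both reference genes had a higher time effect in roots, also adjusted over the list alone. Without a filter on low values 285 genes were called higher and 255 lower for the treatment difference. The time comparison also compares harvest hours, and within tissues limma called 0 genes for time (534 in roots and 416 in shoots at an unadjusted p under 0.05, and 2326 in shoots with the libraries labelled 20 µM exchanged).

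Roots and shoots differed in leaf photosynthesis genes and in some genes of transport and hormones. The 5 photosynthesis genes were all higher in shoots by limma, with CAB2R at 372.04 ± 111.05 RPKM in shoots and 15.66 ± 23.32 RPKM in roots (SD, n = 5 each; log2 difference 5.44 ± 0.62 SE, adjusted p from limma = 0.000139, higher in 5 of 5 conditions). ACO1, an enzyme of ethylene synthesis, was at 42.1 to 83.6 RPKM in shoots. In roots it was at 1.8 RPKM or less and listed at 0 in 1 library (log2 difference 5.01 ± 0.35 SE, adjusted p from limma = 1.85e-05, higher in 5 of 5 conditions). Catalase gene CATA (log2 difference 3.68 ± 0.84 SE), PIP2;6 (3.14 ± 0.64), LHY (2.32 ± 0.58) and Lsi6 (2.22 ± 0.68, adjusted p from limma = 0.0314) were higher in shoots as well. In roots, the fermentation gene ADH2 (−4.62 ± 0.60 SE), the tonoplast channel TIP2;1 (−4.39 ± 0.71), the copper transporter HMA5 (−3.87 ± 0.68) and the zinc and cadmium transporter HMA2 (−2.80 ± 0.43) were higher. Lsi2 and the phosphate transporter PT2 were listed at 0 in all 5 shoot libraries and had root values of 1.3 to 103.9 and 5.4 to 18.5 RPKM.

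By list, limma over all genes called 3 of 8 abscisic acid, 3 of 3 ethylene and 4 of 8 lipid genes higher in shoots and none lower, and 4 of 4 auxin genes, among them GH3.8, IAA20 and GH3.2, lower in shoots and none higher. Of 10 glutathione S-transferases 2 were higher and 6 lower in shoots, of 9 WRKY genes 2 and 4, of 6 zinc, copper and cadmium transporters 1 and 3, of 9 antioxidant enzymes 3 and 1, and of 11 aquaporins 1 and 3 (4 and 3 when adjusted over the list alone). Phosphate genes gave 0 higher and 3 lower of 8, and 1 and 5 when adjusted over the list alone, and the root uptake markers 0 higher and 2 lower of 6. In all, limma with the 5 conditions as blocks called 3068 of 18667 genes higher and 2324 lower in shoots, and recovered 80% of simulated log2 changes of 2. That simulation left out how tissue differences vary over the conditions, so the share may be too high. Without the 20 µM 6 h pair the lower count was 1478. The 2 tissues were compared over 5 pairs of unlike conditions, so these p-values measure how evenly a difference held over the conditions and not a spread between replicates.

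In roots, miR156j had the largest difference of the miRNAs considered. It went from a value of 2208.9 in the untreated library to 53.2, 92.4, 125.3 and 110.1 at 20 and 80 µM for 6 h and 20 and 80 µM for 24 h, a mean log2 change of −4.45 ± 0.48 (SD over the 4 treated libraries). Also at least 2-fold lower in all 4 were miR1423b (100 untreated; 8.6, 6.1, 27.7 and 10.3 treated), miR444c.1 (308.0; 59.7, 39.7, 142.6 and 61.5) and miR160e (137.5; 13.3, 52.7, 41.0 and 45.5), so that 4 of 14 miRNAs were lower and 0 higher. In shoots miR319b (172.7 untreated; 24.6, 39.0, 37.4 and 24.3 treated) and miR820c (121.2; 22.2, 51.3, 43.6 and 30.1) were lower in all 4, 2 of 16, and 0 were higher. Summed miRNA values were 9093.6 in the untreated root library and 3351.0, 3852.7, 8598.8 and 2921.0 in the treated ones, in the same order. In shoots they were 6640.2 untreated and 3932.6, 4281.8, 5414.5 and 5262.0 treated. miR1423b and miR160e in roots and miR319b and miR820c in shoots reached the minimum of 100 only in the untreated library. The rule could thus call these lower but not higher. Headers of 3 treated shoot miRNA files name another group than their labels, which leaves counts over all 4 as they are. Under median ratio scaling the root counts were 1 higher and 2 lower and 1 was lower in shoots, and with a pseudocount of 100 only 1 root and 0 shoot miRNAs were lower. That scaling takes its factors from only 4 miRNAs in roots and 6 in shoots. Without the root 20 µM 24 h library 7 were lower, while 1 shoot miRNA was higher without the 80 µM 6 h library. The largest mean increases, miR812j in roots (15.5 untreated; 224.3, 4.2, 212.2 and 3.5 treated) and miR393 in shoots (13.9; 34.2, 16.6, 98.2 and 125.3), did not hold at 2-fold in all 4.

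Between the tissues, miR166l was higher in shoots by 2.58 ± 0.52 (log2 difference and SE; adjusted p from limma = 7.51e-05) and miR319b lower by a difference of −2.46 ± 0.52 (adjusted p from limma = 8.6e-05). Of 19 miRNAs tested by limma, 5 were higher in shoots (with miR393b-3p, miR164f, miR396e and miR393) and 4 lower (with miR1432, miR166n and miR171f). Median ratio scaling gave 3 higher and 4 lower, and reassigning the 3 shoot libraries by their header codes gave 1 and 2. The scaling factors rest on only 3 miRNAs that reached the minimum in every library. Without the 80 µM 6 h pair 1 was higher, and without the 80 µM 24 h pair 3 were.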

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

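The shoot label test and the correlation with exchanged libraries were written before their results were seen; the tests of an arsenite effect on the clock, of depth, of a few abundant genes and of shoot RNA, and the counts of other splits, were chosen after the result was seen.

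Among the named genes of the lists, 8 went opposite ways in the 2 tissues. Each changed at least 2-fold the same way in all 4 treated libraries of 1 tissue. In all 4 of the other it went the opposite way by any amount, with no minimum RPKM. IRT1 averaged 0.6 RPKM in shoots and SD1 1.16 RPKM in roots, so their directions there rest on low values. The 8 genes were picked by these directions and not by a test. None of these differences passes adjustment over all genes by limma. LEA3 was higher in treated roots (mean log2 change 3.84) and lower in treated shoots (−5.67), a difference of 9.51 (adjusted p from limma = 0.643). APR1 had a mean log2 change of 2.88 in roots and −1.38 in shoots, a difference of 4.26 (adjusted p from limma = 0.643). JAZ11 differed by 2.83 (1.90 in roots, −0.92 in shoots; adjusted p from limma = 0.652) and ABA8ox2 by 3.19 (2.37 and −0.82; adjusted p from limma = 0.765). IRT1 differed by −3.72 (−3.27 in roots, 0.45 in shoots; adjusted p from limma = 0.643), CAB1R by −3.32 (−2.72 and 0.60; adjusted p from limma = 0.643) and RBCSa by −2.88 (−2.27 and 0.61; adjusted p from limma = 0.702). SD1, a gibberellin 20-oxidase gene, differed by −3.25 (−2.0 in roots, where it is listed at 0 at 80 µM and the size depends on the pseudocount, and 1.24 in shoots; adjusted p from limma = 0.643). Further, 24 genes were at least 2-fold higher in all 4 treated root libraries and lower in all 4 treated shoot libraries, with 6.2 for independent lists; this difference was not tested.

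The clock readout and the header codes of the shoot mRNA libraries at 20 µM both go against the labels. The library labelled 20 µM 6 h lay 1.09 log2 units farther from the 80 µM 6 h library than from the mean of the untreated and 80 µM 24 h libraries, which is consistent with a wrong label; an exchange of the 2 labels also predicted that shoot dose differences at 6 h and 24 h would correlate above 0.2 across genes; exchanged they gave −0.009, with a spread of 0.011 over resampled genes, against −0.314 as labelled, so the value above 0.2 was not found and a value below 0 is not shown either. The bound for this test was made to take account of that spread after the value was seen. Values seen later go with an exchange, since exchanged libraries raised the genes at an unadjusted p under 0.05 by limma from 416 to 2326 for time in shoots and from 1846 to 2401 for dose (0 called after adjustment in each), and the library labelled 20 µM 24 h correlated across genes best with 80 µM 6 h (0.950, against 0.926 for that labelled 20 µM 6 h). An arsenite effect on the clock and the genes that follow it, without any wrong label, is not excluded. The root library at 80 µM and 24 h, whose label and code agree, had a readout of −1.69, like the 6 h roots. In roots at 20 µM, though, the readouts went with the labelled hours, at −1.15 after 6 h and 1.45 after 24 h, each in 1 library. Such an effect would also leave the exchanged header codes unexplained.

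In the root library at 80 µM and 6 h 6794 of 13959 genes were at least 2-fold lower than untreated. The value of 1 read, 0.97 times that in the untreated root library, showed no lower depth, where at least 1.5 was predicted. That estimate could not go above about 1.5 and rests on 130 genes, so it does not exclude lower depth. A larger share of the 100 highest genes (15.4% against 8.66%) accounts for a log2 shift of −0.11, smaller than the median change of −0.928. Lower depth, differences in RNA quality and a treatment effect all stay open. RNA quality was not tested. A treatment effect has no replicate of this library and no untreated plants at that hour.

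Leaf photosynthesis genes were highest in the untreated root library, at a median of 15.9% of their level in untreated shoots over 5 genes. Shoot RNA in that library would bring all abundant shoot transcripts at a like ratio, but over 471 genes with at least 100 RPKM in untreated shoots the 5th percentile of the ratio was 0.31%. LEA3, at 245.1 RPKM in untreated shoots, stood at 4.5 RPKM there. A lower level after treatment and a difference of this library alone stay open, as untested, since untreated roots have 1 library.

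Other splits of the same libraries show whether chance can be excluded. For roots against shoots 1 of 100 splits, the real one, called as many genes (5392, highest other 1), and for miRNAs 1 of 100 (9, highest other 4), which excludes chance at 0.05 only for splits that ignore the 5 conditions. Of the 16 splits that exchange the tissues within conditions the real one also called the most genes and miRNAs (highest other 0 for both), but 16 are too few for a share under 0.05. For dose the real split called 0 genes by limma (1846 at an unadjusted p under 0.05), 32 of 35 splits called as many and the highest other called 10. For time it called 0 (350 at an unadjusted p under 0.05), 32 of 35 called as many and the highest other called 0. With 0 calls in the real split every split with a value calls as many, so these counts decide nothing about chance for dose or time; 3 splits of each gave no value.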

How the results depend on the processing

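One alternative, leaving out both shoot libraries labelled 20 µM, was chosen after seeing the data. Of 1649 values recomputed, 1536 stayed within 1.5 times (counts), on the same side of the test or within their spread, 113 moved, 14 of them single genes, miRNAs or pairs, and 0 called values changed sign. Uncalled medians that changed sign under a scaling stand in the report. No paired analysis was possible because the labels number every library 1, so groups share fewer than 2 numbers; this concerns replicate numbers, since conditions, or tissue with time or dose, were blocks in the limma models over both tissues. Absolute mRNA depth is unknown, and low genes are limited by rounding to 1 decimal; except where stated, the cause was not tested.

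With a pseudocount of 5, which shrinks differences of low genes by construction, genes 2-fold higher and lower in all 4 treated libraries went from 718 and 1075 to 417 and 439 in roots and from 77 and 226 to 16 and 120 in shoots, and dose differences at both times from 1062 and 2324 to 665 and 957 in roots and from 116 and 320 to 26 and 92 in shoots. Against untreated roots, 1031 were higher and 1065 lower at 20 µM 24 h, 1056 lower at 20 µM 6 h and 3191 lower at 80 µM 24 h; between doses 2838 root genes were lower at 6 h and 1879 at 24 h. Against untreated shoots, 354 and 698 were higher and lower in the library labelled 20 µM 6 h, 762 and 893 in that labelled 20 µM 24 h, 600 and 1017 at 80 µM 6 h, and 2327 lower at 80 µM 24 h; between doses 954 and 1024 at 6 h and 2687 lower at 24 h. Limma then called 5 genes higher for dose in roots. Root medians became 1.07 for abscisic acid, 0.88 for glutathione S-transferases, −0.29 for lipid, −1.73 for nitrogen transport and −2.01 for photosynthesis, and the shoot abscisic acid median −0.56. With a pseudocount of 0.1 the root abscisic acid and glutathione S-transferase medians were 3.25 and 3.05 and the shoot heat shock median −1.68.

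Without a filter on low values more genes were considered. In all 4 treated libraries 1752 root and 697 shoot genes were lower, and 220 and 538 shoot genes were higher and lower with dose at both times. Higher and lower root genes were 2845 and 4148 at 20 µM 6 h, 2430 and 4308 at 20 µM 24 h, with 11446 and 8188 lower at 80 µM 6 h and 24 h; between doses 8624 were lower at 6 h, and 3348 higher and 5646 lower at 24 h. In shoots they were 1785 and 3008 in the library labelled 20 µM 6 h, 2365 and 3174 in that labelled 20 µM 24 h, 2309 and 3253 at 80 µM 6 h and 1850 and 7494 at 80 µM 24 h; between doses 3361 and 2978 at 6 h and 7049 lower at 24 h. Limma then called 4 genes higher and 355 lower in treated roots, 382 lower in treated shoots, and 285 higher and 255 lower for the difference between them, of 31441 tested. Genes listed at 0 in all treated libraries of a tissue leave no residual there, so these limma calls can rest on the untreated library alone. The root medians became −0.47 for cytokinin, −0.07 for lipid and −0.93 for nitrogen transport.

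Rescaled RPKM gave root medians of 2.91 for glutathione S-transferases, −0.13 for phosphate and −0.53 for zinc, copper and cadmium transport. Exchanging the shoot libraries labelled 20 µM gave 1417 higher genes for 6 h and 842 for 24 h, and 1100 and 951 higher and lower between doses at 6 h; without both, 191 and 554 shoot genes were higher and lower in the treated libraries left.

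For miRNAs, no filter gave 19 higher and 13 lower in shoots than in roots, reassigning 3 shoot libraries 1 and 2, no condition block 3 higher and a pseudocount of 100 2 higher. That pseudocount left 1 lower in treated roots and 0 in treated shoots. Median ratio scaling gave 1 higher and 2 lower in treated roots, 1 lower in treated shoots and 3 higher in shoots than in roots.

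Leaving out 1 treated library gave 799 to 1018 higher and 1117 to 1801 lower root genes (1801 without 20 µM 24 h, 1636 without 20 µM 6 h), and 92 to 244 higher and 295 to 408 lower shoot genes (244 without 80 µM 24 h, 133 without the library labelled 20 µM 6 h, 408 without 80 µM 6 h). Fewer libraries must then pass, so these counts can only grow in the genes considered. For miRNAs it gave 0 higher and 4 to 7 lower in roots (7 without 20 µM 24 h) and 0 to 1 higher (1 without 80 µM 6 h) and 2 to 3 lower in shoots. Leaving out 1 condition gave 2216 to 2935 genes higher and 1478 to 2274 lower in shoots than in roots (1478 without 20 µM 6 h), and 1 to 5 miRNAs higher (1 without 80 µM 6 h, 3 without 80 µM 24 h) and 3 to 4 lower. Leaving out 1 pair, limma called 0 to 15 genes higher and 0 to 4 lower for dose (15 and 4 without the shoot 24 h pair) and 0 for time.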

Other observations

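The test of the miR156 targets was written before its result was seen; its bound was made to take account of the spread over genes after the value was seen.

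Cell division genes, a list added later, were lower in roots at the higher dose. PCNA, the sliding clamp of DNA replication, stood at 28.5 RPKM untreated, at 14.3 and 1.4 RPKM after 6 h in 20 and 80 µM, and at 17.6 and 6.3 RPKM after 24 h. The cyclin-dependent kinase gene CDKB2 stood at 25.7 RPKM untreated, at 12.5 and 1.7 RPKM after 6 h, and at 10.6 RPKM and a listed 0 after 24 h. The list median over 5 genes was −1.89 (percentile 0.68) for the mean of the 4 treated root libraries, with 0 members 2-fold lower in all 4, and −2.04 (percentile 0.8) for dose, and limma called 4 lower for dose in roots when adjusted over the list alone and 0 over all genes (2892 at an unadjusted p under 0.05). The dose median was −1.30 with a pseudocount of 5 and −3.78 with 0.1, and 3 of the 5 genes are listed at 0 in a treated library. In shoots the median over 3 genes was −1.43 (percentile 0.21), with PCNA at 19.2 RPKM untreated and at 1.7 RPKM at 80 µM 24 h.

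Published targets of other miRNA families, with identifiers from general knowledge alone, can be set beside their miRNAs in roots. The 3 measured targets of the miR160 family, auxin response factor genes, had a median log2 change of −1.57 while miR160e was lower in all 4 treated libraries. The medians were −0.52 over 3 targets of miR166, −0.68 over 4 of miR167, −1.0 over 3 of miR168, −0.65 over 2 of miR171 and −0.74 over 2 of miR393. Single targets were at 1.31 for miR395, −1.43 for miR396, −1.22 for miR399 and 0.92 for miR444. Over all genes considered, the median change against untreated roots was −0.224 and −0.928 after 6 h in 20 and 80 µM, and −0.205 and −0.473 after 24 h. The medians for targets of miR166, miR167, miR171 and miR393 lie within that range.

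A lower level of miR156j in treated roots could leave its targets, the SPL transcription factor genes, higher, and that was tested as a hypothesis. Of 7 SPL genes 3 were measured in roots, with mean log2 changes of −2.31, −1.80 and 0.54. Their median was −1.80 (SD 1.52 over the 3 genes), where at least 0.5 was predicted, so these 3 genes give the hypothesis no backing.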
